A study of Homo sapiens with 29 samples.

How the data were processed

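Gene expression was measured on oligonucleotide arrays in 29 human samples in 3 groups. Per the labels, total RNA was extracted with Trizol and amplified in a double round with a commercial kit before hybridisation. The T-lymphoblastic lymphoma (T-LL) samples came from lymphoma tissue. The T-cell acute lymphoblastic leukaemia (T-ALL) and B-cell acute lymphoblastic leukaemia (B-ALL) samples came from bone marrow.

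The deposited table gives an intensity on a linear scale for each of 22283 probe sets in each of 29 columns. The mean intensity after trimming 2% of the probe sets at each end was between 150 and 150.1 in every column, so each array had already been scaled by the authors to a common mean. How the authors summarised the probes of a probe set is not given in the sources used here. The lowest value was 0. The labels matched all columns, with 0 columns of no sample. There was 1 pair of identical columns: T-ALL replicates 5 and 6 held the same values in all 22283 probe sets. They were used as 1 array, under the name T-ALL replicate 5, which left 28 independent arrays: 9 T-LL, 9 T-ALL and 10 B-ALL. The labels do not say whether any patient gave more than 1 sample.

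Intensities were used as scaled by the authors. Values under a floor of 8.8, the 20th percentile of all values, were set to the floor, and log2 was taken, so the lowest log2 value is 3.14. A probe set had to exceed the floor on at least 9 arrays. Probe sets were joined to gene symbols, with renamed genes given their current symbol. The 19065 probe sets with 1 gene were kept, and 2169 probe sets with no gene, 1043 with several genes and the control probe sets were left out. To keep the text free of anything that shows the sex of a donor, 31 probe sets of XIST, TSIX and genes of the Y chromosome were left out too. Each of 11939 genes was represented by its probe set with the highest mean log2 intensity over the 28 arrays, without regard to group, and 11193 genes passed the filter. Of these, 4261 had more than 1 probe set. The other probe sets of a named gene were not always called or of the same sign, which is given below for some genes only. A fold change is 2 to the power of the log2 difference. Where arrays of a group lie at the floor, the fold depends on the floor. Where all arrays of a group do, it is given as a bound. The array files name no genome build, so no coordinates are given.

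All calls of single genes are from limma 3.58.1 in R 4.3.3: 1 mean per group, all 28 arrays in a single model with 25 residual degrees of freedom, the default moderated variance, and Benjamini-Hochberg adjustment over the 11193 genes within each comparison. A gene was called at an adjusted p under 0.05. The 3 comparisons were T-ALL minus B-ALL, T-LL minus T-ALL and T-LL minus B-ALL. Overlaps between comparisons that share a group were set beside the overlap of independent lists and 100 simulations of unchanged groups that share arrays in the same way. In addition, the shared arrays were split at random 20 times, so that each comparison had arrays of its own.

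A total of 30 gene lists were tested as sets with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 90 list tests. A list needed at least 5 measured members. Every list count is also given as adjusted over the list alone, and every called list with its adjusted p when camera estimates the correlation from the data. The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule takes, in each comparison, the 8 genes with the largest positive and the 8 with the largest negative log2 difference among those called, and for each list described up to 4 members with the smallest adjusted p in the direction of most of its called members. How many members were named per list was set after the values were seen, and the lower-ranked ones, with larger adjusted p, were left out. CD3D, CD7 and CD79A are always given, as a check of the labels. Variable segments of immunoglobulins and T-cell receptors are never named. A few other genes are named and said to be chosen after their values were seen.

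The procedure after the filter and the choice of probe set was tested on simulated data made from the arrays, in 20 draws per comparison with 200 changed genes. Each draw took the arrays' deviations from their group means, over all 3 groups and with replacement, so an array could occur repeatedly. How far that changes the share of false calls was not tested. The procedure recovered 26.4%, 23.8% and 26.3% of 2-fold changes and 77.3%, 75.9% and 78.1% of 4-fold changes in the order of comparisons above. Of the calls, 6.92%, 11.2% and 5.57% were false, and 0 had the wrong sign. With no list effect in the simulated data, camera with the preset correlation still called a median of 19, 18.5 and 17 of 90 list tests, so a list call with the preset correlation alone carries little weight.

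Array quality was described by the median and the 75th percentile of intensity, the percent of probe sets above the floor, the percent of signal in the brightest 10 probe sets, the log2 ratio of the 3' to the 5' control probe set of actin and of GAPDH, and the mean of the T-lineage list minus that of the B-lineage list. These 7 measures were compared between groups in 21 two-sided exact permutation tests with Benjamini-Hochberg adjustment. The number of arrays limits the precision of every value.

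There were 19 alternatives apart from 28 runs that each left out 1 array. They changed the scaling (quantile normalization, or division of each array by its 75th percentile), the floor, the filter, the choice of probe set, the variance model, the array weights, the arrays in the model, the size of change required, the list test, the replicate number of the titles as a block, and the means of the fibroblast and granulocyte lists as covariates. The 3 added after seeing the data kept the identical columns as 2 arrays, left out 2 arrays whose lineage genes went against their label, or took the actin 3'/5' ratio as a covariate. For each result, 100 splits of the samples, the real one included, were compared. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.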

Results

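The data collected were array intensities of 22283 probe sets in 9 samples of T-LL, 10 of T-ALL and 10 of B-ALL. T-LL and T-ALL are cancers of immature T cells, told apart in the clinic by whether the disease mainly forms masses in lymphoid tissue or mainly fills the marrow, and B-ALL is a cancer of immature B cells. After the identical pair of T-ALL columns was merged, n was 9 arrays for T-LL, 9 for T-ALL and 10 for B-ALL. The median intensity of an array lay between 32.2 and 65.3, against the floor of 8.8, and between 74.8% and 87.6% of probe sets lay above the floor. All T-LL samples were lymphoma tissue and all leukaemia samples were marrow, so disease and tissue differ together in every comparison that involves T-LL.

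The groups also differed in quality measures. The log2 ratio of the 3' to the 5' actin probe set, which increases as RNA is shortened, was 6.39 ± 0.55 (SD, n = 9) in T-LL, 5.49 ± 0.74 (n = 9) in T-ALL and 4.80 ± 0.48 (n = 10) in B-ALL. It was higher in T-LL than in T-ALL (exact permutation p = 0.012, adjusted p = 0.027 over 21 tests) and than in B-ALL (exact permutation p = 3.25e-05, adjusted p = 3.41e-04), and the difference between T-ALL and B-ALL did not pass (exact permutation p = 0.028, adjusted p = 0.059). The same ratio for GAPDH was 4.10 ± 0.41 in T-LL, 3.47 ± 0.27 in T-ALL and 3.74 ± 0.46 in B-ALL, and it passed between T-LL and T-ALL (exact permutation p = 8.64e-04, adjusted p = 0.0030). It did not pass between T-LL and B-ALL (exact permutation p = 0.088, adjusted p = 0.132) or between T-ALL and B-ALL (exact permutation p = 0.141, adjusted p = 0.175). The actin and GAPDH ratios thus did not order the groups alike. The 75th percentile of intensity was 158.9 ± 5.11 in T-LL, above the 129.9 ± 15.6 in T-ALL (exact permutation p = 2.06e-04, adjusted p = 0.0014) and the 133.9 ± 18.1 in B-ALL (exact permutation p = 2.92e-04, adjusted p = 0.0015). The percent of signal in the brightest 10 probe sets was 3.08 ± 0.65 in T-LL, 3.09 ± 0.58 in T-ALL and 4.28 ± 0.87 in B-ALL. It was lower than in B-ALL both in T-ALL (exact permutation p = 0.0033, adjusted p = 0.0098) and in T-LL (exact permutation p = 0.0043, adjusted p = 0.011), so the marrow groups were not alike in every measure.

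T-ALL and B-ALL, both from marrow, were compared to see which genes separate T-lineage from B-lineage leukaemia. In T-ALL 15 of 22 genes of the T-lineage list rose, and 12 of 22 of the B-lineage list and 9 of 12 of the HLA class II list fell. With an estimated correlation the T-lineage list passed and the other lists did not (adjusted p = 0.033, 0.269 and 0.201 with an estimated correlation). SH2D1A, an adaptor protein of T and NK cells, had a log2 intensity of 10.61 ± 1.95 (SD, n = 9) in T-ALL and 3.69 ± 0.90 (n = 10) in B-ALL, a 121-fold difference (log2 difference 6.92, SE 0.77, adjusted p = 1.91e-06, above the B-ALL mean in 9 of 9 T-ALL arrays). CD3D, a chain of the T-cell receptor complex, was 29.5-fold higher (12.05 ± 1.60 against 7.17 ± 0.68, SE of the log2 difference 0.59, adjusted p = 7.56e-06, 9 of 9 arrays). CD24, a surface protein of B-cell precursors, was 30.6-fold lower (6.60 ± 2.82 against 11.54 ± 0.99, SE 0.93, adjusted p = 0.0010, below the B-ALL mean in 8 of 9 arrays).

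Of 11193 genes tested, limma called 1037, of which 527 were higher and 510 lower in T-ALL, and 828 of the calls were at least 2-fold. The other genes with the largest increases were ALDH1A2, an enzyme of retinoic acid synthesis (41.0-fold, adjusted p = 4.37e-04), CD3G (30.2-fold, adjusted p = 2.58e-05), LAT, the linker that relays T-cell receptor signals (22.4-fold, adjusted p = 2.13e-05), TRBC1, a constant region of the receptor's beta chain (19.6-fold, adjusted p = 3.91e-05), TRAT1 (18.7-fold, adjusted p = 5.89e-05) and S100A10 (17.8-fold, adjusted p = 1.81e-05). Each of these 6 was above the B-ALL mean in 9 of 9 arrays. Of the 2 probe sets of ALDH1A2 1 was called, with log2 differences from -0.61 to 5.36. The largest decreases, after CD24, were in CHST15, a sulfotransferase (log2 difference -4.42, adjusted p = 1.26e-06), PSD3 (-4.28, adjusted p = 1.53e-04), BLNK, the linker of B-cell receptor signalling (-4.11, adjusted p = 2.58e-04), MEF2C (-3.94, adjusted p = 0.018), INSR, the insulin receptor (-3.83, adjusted p = 1.62e-04), PAX5, the transcription factor that commits cells to the B lineage (-3.81, adjusted p = 0.0010), and LRP5L (-3.76, adjusted p = 1.68e-04). These 7 were below the B-ALL mean in 7 to 9 of the 9 arrays. For MEF2C, INSR and PAX5, 1 probe set each was called, out of 3, 2 and 2.

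Of 22 measured members of the T-lineage list, 15 rose and 0 fell in T-ALL (18 rose when adjusted over the list alone), with a median log2 difference of 2.82 and a camera adjusted p = 6.21e-22. This was the 1 list called in this comparison that also passed with an estimated correlation (adjusted p = 0.033 with an estimated correlation). In the B-lineage list 12 of 22 members fell and 0 rose (17 fell when adjusted over the list alone), with a median of -1.90 and an adjusted p = 4.08e-10 (adjusted p = 0.269 with an estimated correlation). Among them were BTK, a kinase of B-cell receptor signalling (-2.85, adjusted p = 3.15e-04), and CD72, a receptor on B cells (-3.38, adjusted p = 4.37e-04). In the HLA class II list 9 of 12 members fell and 0 rose (9 fell when adjusted over the list alone). The list median was -2.51 (adjusted p = 2.88e-10, and adjusted p = 0.201 with an estimated correlation). Those that fell included CIITA, the regulator that switches on class II genes (-3.27, adjusted p = 5.89e-05), HLA-DPA1 (-3.72, adjusted p = 3.15e-04) and HLA-DMA (-2.48, adjusted p = 4.37e-04).

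Lists of other T-ALL programmes had fewer called members. In the cortical thymocyte list, 2 of 13 members rose and 0 fell (4 rose when adjusted over the list alone), namely CD4 (1.23, adjusted p = 0.0056) and CD1B, an antigen-presenting molecule of cortical thymocytes (3.52, adjusted p = 0.038). The list had a median of 0.84 and an adjusted p = 0.010 (adjusted p = 0.542 with an estimated correlation). In the list of transcription factor oncogenes of T-ALL, 2 of 10 members fell and 0 rose (2 fell when adjusted over the list alone). Its members had a median log2 difference of -0.77 (adjusted p = 0.032, and adjusted p = 0.269 with an estimated correlation). Those that fell were MEF2C and BCL2, a survival protein and not a transcription factor (-0.84, adjusted p = 0.028). The adhesion and homing list was not called (adjusted p = 0.053): 3 of 18 members rose and 1 fell (7 and 3 when adjusted over the list alone), with ICAM3 (1.11, adjusted p = 0.011) and ICAM2 (1.63, adjusted p = 0.015), ligands of leukocyte integrins, among those that rose.

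In the immediate early and heat shock list 3 of 19 members fell and 1 rose (6 and 2 when adjusted over the list alone), with falls in DUSP1, a phosphatase of MAP kinases (-1.58, adjusted p = 0.019), and NR4A2, a nuclear receptor (-2.74, adjusted p = 0.026). Camera gave the list an adjusted p = 0.033 at a median of -0.75, and adjusted p = 0.661 with an estimated correlation. In the ribosomal protein list 7 of 36 members fell and 0 rose (17 fell when adjusted over the list alone), with a median of -0.52 and an adjusted p = 3.38e-07 (adjusted p = 0.640 with an estimated correlation). RPL37 (-1.06, adjusted p = 0.0024) and RPL22 (-1.04, adjusted p = 0.0077) were examples, and quantile normalization brought the list's median to -0.09 and ended its call (adjusted p = 0.095). The remaining called lists had at most 1 called member: granulocyte (median -0.81, 1 of 18 fell, adjusted p = 0.0087), erythroid (-1.03, 1 of 15 fell, adjusted p = 0.0029), platelet and megakaryocyte (-0.59, 0 of 10, adjusted p = 0.035), cell cycle (0.33, 1 of 32 rose, adjusted p = 0.0069) and oxidative phosphorylation (0.24, 1 of 30 rose, adjusted p = 0.031). Adjusted over the list alone, the counts were 3, 1, 1, 0 and 1. With an estimated correlation, the adjusted p was 0.692, 0.661, 0.518, 0.702 and 0.696 in the same order.

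As a check of the labels, CD7, a surface marker of T cells, was 4.60 ± 1.07 in T-ALL and 3.34 ± 0.44 in B-ALL and was not called (1.26, adjusted p = 0.051), while CD79A, a chain of the B-cell receptor complex, fell by 1.52 (adjusted p = 0.038). Several calls near the threshold changed when any 1 of several arrays was left out. The differences kept their sign and much of their size, such as 2.92 to 3.53 for CD1B and -1.50 to -1.26 for CD79A where the call ended. The calls ended for BCL2 without B-ALL 7 or 9 or T-ALL 5, 7 or 9 (adjusted p 0.051 to 0.059), for CD1B without B-ALL 2 or 9 or T-ALL 2, 3, 4, 5 or 8 (0.052 to 0.095), for NR4A2 without B-ALL 6 or 9 or T-ALL 4 or 5 (0.051 to 0.056) and for CD79A without any of 10 arrays (B-ALL 1, 3, 4, 9 or 10, or T-ALL 2, 4, 5, 7 or 9; 0.053 to 0.084), and CD7 was called without B-ALL 1 or 7, T-ALL 1 or 7, or T-LL 1, 2, 3, 4 or 9 (0.020 to 0.049). Quantile normalization also ended the calls of the platelet, cell cycle and oxidative phosphorylation lists (adjusted p 0.062, 0.097 and 0.139). With the actin 3'/5' ratio as a covariate, 324 genes were called, and the cortical thymocyte, oncogene, platelet, cell cycle and oxidative phosphorylation lists were not (adjusted p 0.0501 to 0.398).

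**Figure D1:**
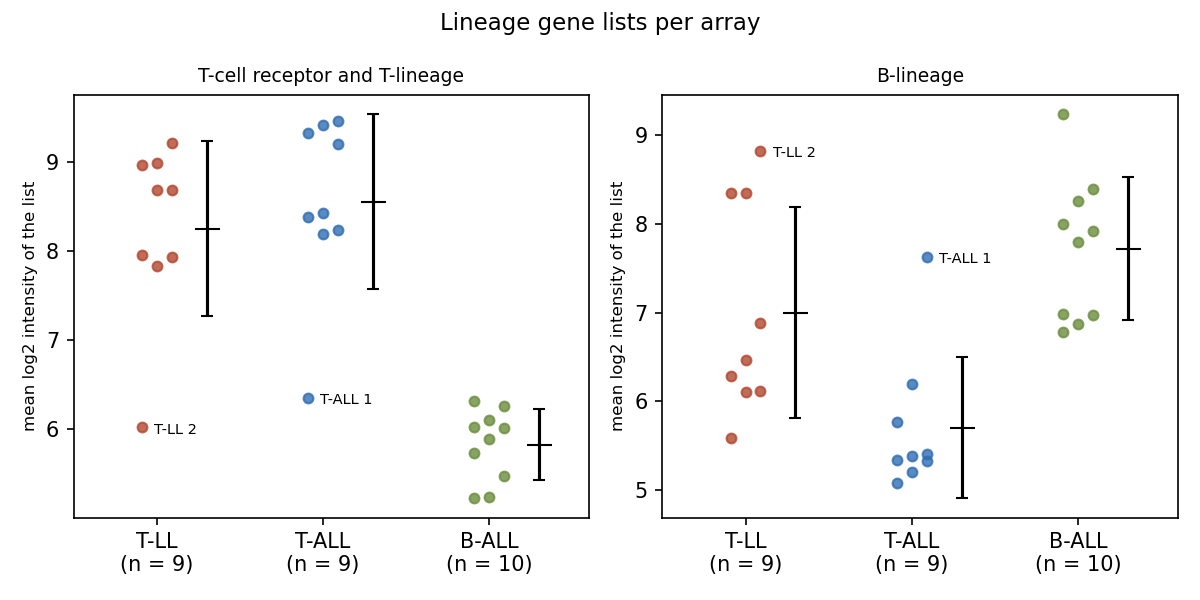
Mean log2 intensity of the T-lineage list and of the B-lineage list on each array, by group; each point is an array, and bars give the group mean ± SD (n = 9 T-LL, 9 T-ALL and 10 B-ALL). The T-lineage mean was 8.25 ± 0.98 in T-LL, 8.56 ± 0.98 in T-ALL and 5.83 ± 0.40 in B-ALL, and the named arrays T-LL 2 (6.02) and T-ALL 1 (6.35) lie near the B-ALL arrays.

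Lineage lists were also read array by array. The mean of the T-lineage list minus that of the B-lineage list was 2.86 ± 1.67 (SD, n = 9) in T-ALL, 1.25 ± 2.04 (n = 9) in T-LL and -1.90 ± 0.72 (n = 10) in B-ALL. It differed from B-ALL in T-ALL (exact permutation p = 2.17e-05, adjusted p = 3.41e-04) and in T-LL (exact permutation p = 5.41e-04, adjusted p = 0.0023). The B-ALL arrays spanned -3.35 to -0.67, and 2 arrays with a T-lineage label lay inside that range: T-ALL 1 at -1.28 and T-LL 2 at -2.81. On T-ALL 1 the T-lineage list had a mean of 6.35, where the other T-ALL arrays had 8.20 to 9.47 and the B-ALL arrays 5.22 to 6.32. Its B-lineage mean was 7.63, where the other T-ALL arrays had 5.07 to 6.19. On T-LL 2 the T-lineage mean was 6.02 against 7.83 to 9.21 on the other T-LL arrays, and the B-lineage mean was 8.83 against 5.59 to 8.36. Across genes, which are not independent replicates, T-ALL 1 had a mean correlation of 0.82 with the other arrays of its label and 0.84 with the B-ALL arrays. For T-LL 2 these means were 0.85 and 0.77. Both arrays were kept. Without them limma called 1374 genes in T-ALL minus B-ALL, 1919 in T-LL minus T-ALL and 3047 in T-LL minus B-ALL, of which 993, 1747 and 2798 were among those called with all 28 arrays.

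T-LL and T-ALL were compared to see how a T-lineage lymphoma in tissue differs from a T-lineage leukaemia in marrow. Most genes of the fibroblast and collagen matrix list rose in T-LL (24 of 27), and it was the 1 list called here that also passed with an estimated correlation (adjusted p = 0.033 with an estimated correlation). Fewer genes rose in the macrophage, vessel and lymph node chemokine lists (10 of 20, 7 of 15 and 6 of 15), and 6 of 15 erythroid and 5 of 18 granulocyte genes fell. With an estimated correlation the adjusted p of these lists was 0.269 to 0.518. COL3A1, a fibrillar collagen, had a log2 intensity of 10.53 ± 1.54 (SD, n = 9) in T-LL and 4.19 ± 0.63 (n = 9) in T-ALL, an 80.8-fold difference (log2 difference 6.34, SE 0.49, adjusted p = 1.70e-10, 9 of 9 T-LL arrays above all T-ALL arrays). VWF, the von Willebrand factor made by endothelium and megakaryocytes, was 30.5-fold higher (8.51 ± 0.46 against 3.58 ± 0.89, SE 0.29, adjusted p = 2.44e-13, 9 of 9 arrays). HBB, the beta chain of adult haemoglobin, was 27.6-fold lower (7.87 ± 1.79 against 12.66 ± 1.80, SE 0.81, adjusted p = 9.89e-05, below the T-ALL mean in 9 of 9 arrays).

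Of 11193 genes, limma called 2170, of which 1534 were higher and 636 lower in T-LL, and 1692 were at least 2-fold. The split into higher and lower depended on the scaling: 70.7% of calls were higher as deposited, 54.6% of 2068 after quantile normalization and 41.6% of 2267 after division by the 75th percentile, with 1632 and 1579 of the 2170 genes still called. The median log2 difference of all genes was 0.13, -0.032 and -0.12 under the 3 scalings. Further genes with the largest increases were FN1, fibronectin (76.1-fold, adjusted p = 3.47e-09), C3, a complement protein (50.3-fold, adjusted p = 1.04e-07, 8 of 9 arrays), CCN1 (47.6-fold, adjusted p = 3.80e-08), A2M, a protease inhibitor (43.5-fold, adjusted p = 1.77e-11), TNS3 (35.7-fold, adjusted p = 1.00e-06) and C1S, a complement protease (31.8-fold, adjusted p = 1.24e-07). All but C3 were above the T-ALL mean in 9 of 9 arrays. The largest decreases were in CXCL8, a chemokine that draws neutrophils (-5.12, adjusted p = 5.24e-04), HBD, the delta chain of haemoglobin (-4.99, adjusted p = 2.71e-04), S100A8, a calcium-binding protein of neutrophils and monocytes (-4.87, adjusted p = 5.33e-04, 8 of 9 arrays), CA1, a carbonic anhydrase of red cells (-3.68, adjusted p = 0.0029), TSC22D3, a gene induced by glucocorticoids (-3.49, adjusted p = 1.23e-06), and KLF6 (-3.41, adjusted p = 4.56e-04). TKTL1 was at the floor on all 9 T-LL arrays and at least 10.4-fold lower than in T-ALL (adjusted p = 0.0021). Of the 2 probe sets each of CXCL8, S100A8, CA1 and TKTL1, 1 was called, and the other CXCL8 probe set differed by -0.77.

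**Figure D2:**
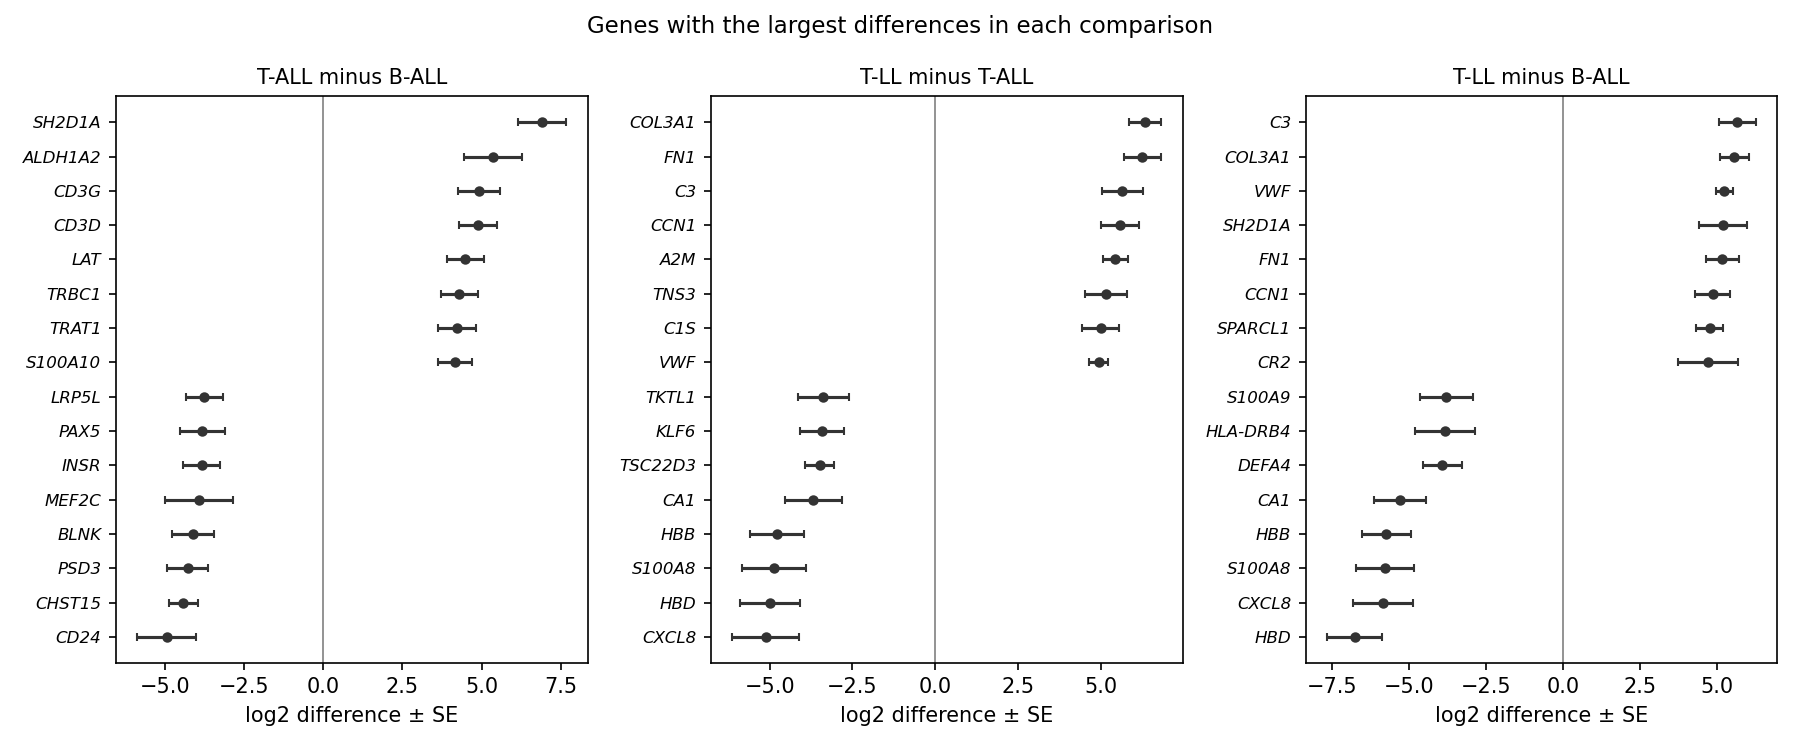
Log2 difference in mean intensity, with bars of ± 1 SE from limma, of the 8 called genes with the largest increase and the 8 with the largest decrease in each of the 3 comparisons. SH2D1A (6.92) leads T-ALL minus B-ALL, COL3A1 (6.34) leads T-LL minus T-ALL, and HBD (-6.78) is the lowest in T-LL minus B-ALL.

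Of 27 measured members of the fibroblast and collagen matrix list, 24 rose and 0 fell in T-LL (24 rose when adjusted over the list alone), with a median of 2.80 and a camera adjusted p = 2.43e-21 (adjusted p = 0.033 with an estimated correlation). COL1A2 (4.63, adjusted p = 9.43e-09) and COL4A1, a collagen of basement membranes (4.73, adjusted p = 4.31e-08), were among them. The list mean was 7.88 ± 0.81 in T-LL, 5.01 ± 0.28 in T-ALL and 5.42 ± 0.50 in B-ALL. In the endothelium list 7 of 15 members rose and 0 fell (8 and 1 when adjusted over the list alone), including TEK, a receptor of angiopoietins (2.74, adjusted p = 4.17e-09), and CDH5, a cadherin of endothelial junctions (2.31, adjusted p = 8.08e-07). Over all its members the median was 1.08 (adjusted p = 0.0010, and adjusted p = 0.269 with an estimated correlation). In the monocyte and macrophage list 10 of 20 members rose and 0 fell (11 rose when adjusted over the list alone). With a median of 1.31, the list had an adjusted p = 1.36e-04 (adjusted p = 0.269 with an estimated correlation). GPNMB, a glycoprotein of macrophages (4.04, adjusted p = 1.18e-07), CCL18, a chemokine of alternatively activated macrophages (4.70, adjusted p = 3.30e-07), and CTSB, a lysosomal protease (2.70, adjusted p = 9.47e-06), were examples. In the lymph node chemokine list, which also holds CCL18, 6 of 15 members rose and 0 fell (8 rose when adjusted over the list alone). The list median was 0.97 (adjusted p = 7.47e-04, and adjusted p = 0.269 with an estimated correlation). CCL19, which guides T cells and dendritic cells into lymph nodes, rose by 3.38 (adjusted p = 1.30e-05), and CXCL13, which guides B cells to follicles, rose by 4.10 (adjusted p = 1.72e-04).

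In the erythroid list 6 of 15 members fell and 0 rose in T-LL (8 fell when adjusted over the list alone), HBB, HBD and CA1 among them. Its members had a median log2 difference of -1.73 (adjusted p = 1.36e-04, and adjusted p = 0.518 with an estimated correlation). In the granulocyte list 5 of 18 fell and 0 rose (6 fell when adjusted over the list alone), with S100A8, RNASE2, a ribonuclease of eosinophils (-1.80, adjusted p = 0.0039), and CTSG, a protease of neutrophil granules (-1.62, adjusted p = 0.014), as examples. Camera gave the list an adjusted p = 9.36e-05 at a median of -0.94, and adjusted p = 0.472 with an estimated correlation. The erythroid list mean was 5.13 ± 0.27 in T-LL, 6.80 ± 1.21 in T-ALL and 7.90 ± 1.66 in B-ALL, and the granulocyte list mean was 4.21 ± 0.35, 5.38 ± 0.77 and 6.38 ± 1.44.

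**Figure D3:**
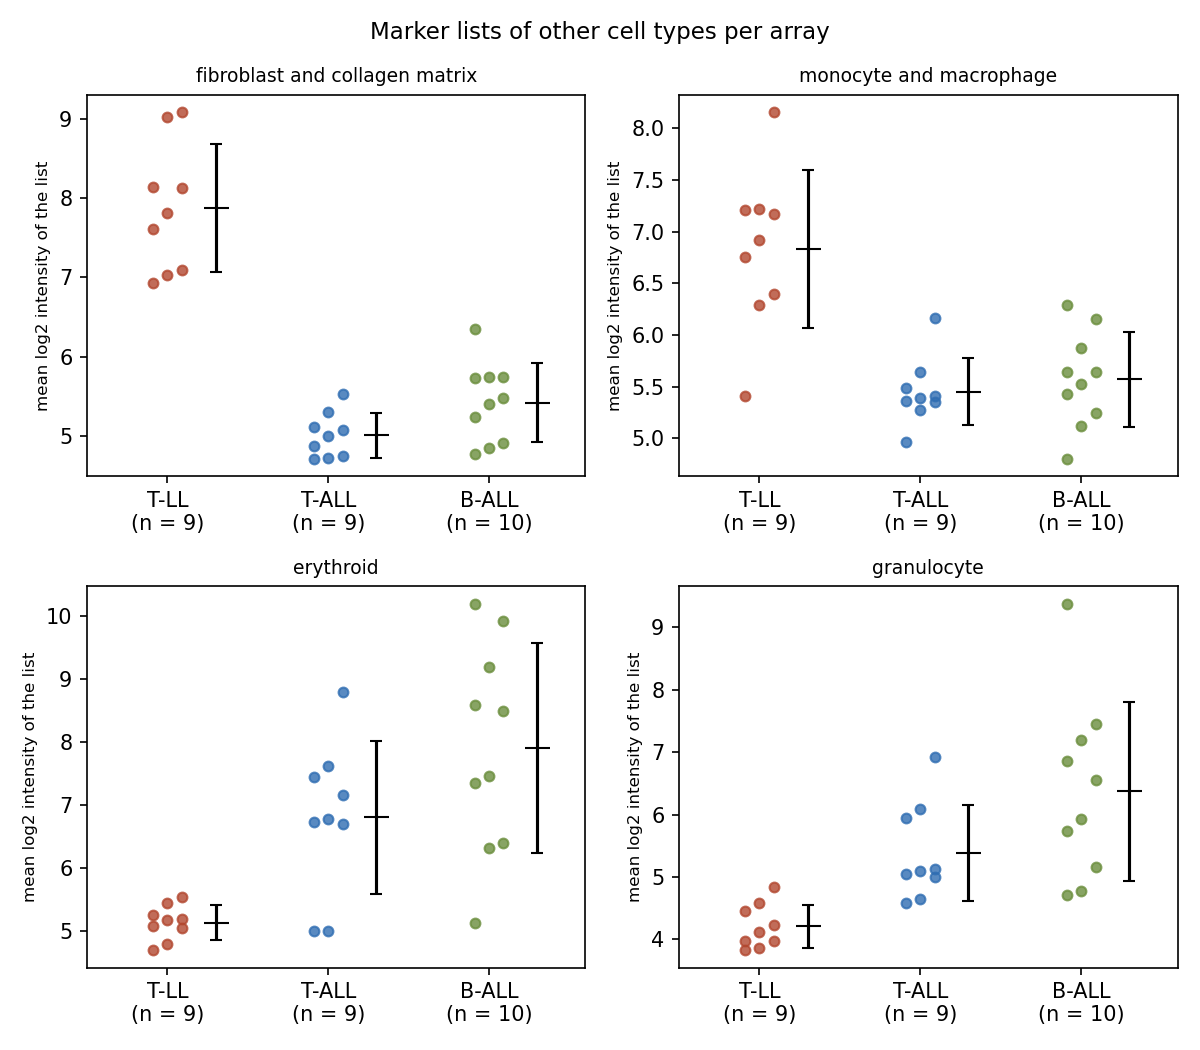
Mean log2 intensity of the fibroblast and collagen matrix, monocyte and macrophage, erythroid and granulocyte lists on each array, by group; each point is an array, and bars give the group mean ± SD (n = 9 T-LL, 9 T-ALL and 10 B-ALL). The lowest T-LL array (6.93) lies above the highest B-ALL array (6.35) in the fibroblast list, and the erythroid and granulocyte means are lowest in T-LL.

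Part of the HLA class II and B-lineage lists rose as well, while in the HLA class I and antigen processing list 0 of 12 members rose or fell (median 0.08, adjusted p = 0.831). In the HLA class II list 6 of 12 members rose and 0 fell (9 rose when adjusted over the list alone), with CIITA higher by 3.44 (adjusted p = 6.40e-06) and HLA-DPA1 by 3.02 (adjusted p = 9.79e-04). Of the 3 probe sets of CIITA 1 was called, with log2 differences from -0.59 to 3.44. Over all members of the HLA class II list the median was 1.64 (adjusted p = 3.89e-04, and adjusted p = 0.468 with an estimated correlation). The HLA class II mean was 9.85 on T-LL 5 (other T-LL arrays 6.96 to 8.40) and 8.69 on T-ALL 1 (other T-ALL arrays 5.21 to 7.17). Without T-ALL 1 and T-LL 2, 9 of 12 members rose (median 2.08, adjusted p = 3.35e-06). In the B-lineage list 9 of 22 members rose and 0 fell (9 rose when adjusted over the list alone). With a median of 1.36, the list had an adjusted p = 0.0082 (adjusted p = 0.696 with an estimated correlation). A few T-LL arrays stood apart: the B-lineage mean was 8.83, 8.36 and 8.35 on T-LL 2, 5 and 6 and between 5.59 and 6.89 on the others. Without T-LL 2 and T-ALL 1, the arrays whose lineage genes go against their label, 11 of 22 rose (median 1.32, adjusted p = 0.0028). Examples were POU2AF1, a coactivator of B-cell transcription (3.18, adjusted p = 0.0014), SPIB, a transcription factor of B cells and plasmacytoid dendritic cells (1.60, adjusted p = 0.0042), and CD72 (2.12, adjusted p = 0.012). In the NOTCH target list 4 of 10 rose and 0 fell (4 rose when adjusted over the list alone), with HEY1, a repressor induced by NOTCH (2.35, adjusted p = 1.53e-05), MYC (2.53, adjusted p = 0.0073) and RUNX3 (2.01, adjusted p = 0.0077) as examples. The list median was 0.81 (adjusted p = 0.030, and adjusted p = 0.269 with an estimated correlation). The T-lineage list was not called (median -0.21, 1 of 22 fell and 0 rose, 1 when adjusted over the list alone, adjusted p = 0.123). With the actin 3'/5' ratio as a covariate it was called lower (adjusted p = 0.0045), and the NOTCH target list was not called (adjusted p = 0.0501).

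In the cell cycle list 9 of 32 members rose and 0 fell in T-LL (16 rose when adjusted over the list alone). Its members had a median log2 difference of 0.84 (adjusted p = 0.0010, and adjusted p = 0.696 with an estimated correlation). A few T-ALL arrays lay low: the list mean was 6.71, 7.18 and 6.63 on T-ALL 1, 9 and 10, between 8.26 and 8.92 on the other T-ALL arrays and between 8.03 and 9.30 on the T-LL arrays. Without T-ALL 1 and T-LL 2, 3 of 32 members rose (median 0.63, adjusted p = 0.042). AURKA, a mitotic kinase (2.53, adjusted p = 2.63e-04), BUB1B, a spindle checkpoint protein (1.67, adjusted p = 0.0036), and MCM3, a part of the replicative helicase (1.22, adjusted p = 0.0036), were examples, and with the actin 3'/5' ratio as a covariate 1 member was called and the list was not (adjusted p = 0.214). In the oxidative phosphorylation list 13 of 30 fell and 0 rose (14 fell when adjusted over the list alone), among them the ATP synthase subunits ATP5F1B (-1.52, adjusted p = 1.86e-04) and ATP5F1C (-1.15, adjusted p = 8.44e-04) and UQCRC2, a part of complex III (-0.98, adjusted p = 0.0014). Camera gave the list an adjusted p = 1.70e-08 at a median of -0.57, and adjusted p = 0.269 with an estimated correlation. The probe sets of ATP5F1C did not all go one way: 3 of 4 were lower and 1 was higher, from -1.33 to 2.29. In the ribosomal protein list 10 of 36 fell and 0 rose (22 fell when adjusted over the list alone), with RPL34 (-1.14, adjusted p = 0.0048) and RPL31 (-0.78, adjusted p = 0.012) as examples. Over all its members the median was -0.62 (adjusted p = 3.93e-10, and adjusted p = 0.518 with an estimated correlation). Its median was -0.26 after quantile normalization and -0.92 after division by the 75th percentile. The T-LL arrays compared here also had the higher 3'/5' ratios of actin and GAPDH.

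Of the genes that check the labels, 0 of 3 were called between T-LL and T-ALL: CD3D was 10.44 ± 1.74 against 12.05 ± 1.60 (-1.61, adjusted p = 0.060), CD7 was 5.54 ± 1.21 against 4.60 ± 1.07 (0.93, adjusted p = 0.124) and CD79A was 5.72 ± 0.85 against 4.84 ± 1.11 (0.88, adjusted p = 0.210). CD3D was called without T-ALL 1 (-2.11, adjusted p = 0.0044) and without T-LL 1, 7 or 8 (adjusted p up to 0.048). It was also called lower after division by the 75th percentile (-1.91, adjusted p = 0.030), with array weights (adjusted p = 0.019), with the identical columns kept (adjusted p = 0.038), without the 2 arrays in doubt (adjusted p = 0.0092) and with the actin ratio as a covariate (-2.15, adjusted p = 0.044). CD79A was called with the replicate numbers as a block (1.11, adjusted p = 0.048). With the fibroblast and granulocyte list means as covariates 2 genes were called, and with the actin 3'/5' ratio as a covariate 1416 were, 1294 of them among the 2170.

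T-LL and B-ALL were compared to see how the lymphoma tissue differs from marrow of the other lineage, so lineage and tissue differ together. Of the matrix and T-lineage lists 22 of 27 and 17 of 22 genes rose, and 11 of 15 erythroid, 13 of 18 granulocyte and 34 of 36 ribosomal protein genes fell. No list passed with an estimated correlation (lowest adjusted p = 0.140 with an estimated correlation), and 10 ribosomal genes fell after quantile normalization. COL3A1 was 46.9-fold higher (log2 10.53 ± 1.54, SD, n = 9, against 4.98 ± 0.95, n = 10, SE of the difference 0.48, adjusted p = 1.98e-09, 9 of 9 arrays), and SH2D1A was 36.5-fold higher (8.88 ± 2.38 against 3.69 ± 0.90, SE 0.77, adjusted p = 1.13e-05, 8 of 9 arrays). Of the 4 probe sets of SH2D1A only 1 was called here, with log2 differences from 0.77 to 5.19. HBD had the largest difference, 110-fold lower in T-LL (4.89 ± 0.85 against 11.67 ± 2.43, SE 0.90, adjusted p = 2.46e-06, 9 of 9 arrays).

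Limma called 3040 of 11193 genes, with 1888 higher and 1152 lower in T-LL and 2251 at least 2-fold. Again the split depended on the scaling: 62.1% of calls were higher as deposited, 53.7% of 3260 after quantile normalization and 39.4% of 3597 after division by the 75th percentile, with 2685 and 2566 of the 3040 genes still called and medians of all genes of 0.02, -0.038 and -0.20. Other large increases were in C3 (50.6-fold, adjusted p = 6.58e-08, 8 of 9 arrays), VWF (37.7-fold, adjusted p = 2.16e-14), FN1 (36.0-fold, adjusted p = 4.86e-08), CCN1 (28.9-fold, adjusted p = 3.38e-07), SPARCL1, a matrix protein (26.9-fold, adjusted p = 1.54e-08), and CR2, the complement receptor of B cells and follicular dendritic cells (25.9-fold, adjusted p = 5.71e-04, 7 of 9 arrays). Of the 6 probe sets of FN1, 4 were called higher and 1 lower, from -0.77 to 6.07. Other large decreases were in CXCL8 (-5.85, adjusted p = 5.71e-05), S100A8 (-5.79, adjusted p = 3.67e-05), HBB (-5.75, adjusted p = 4.38e-06), CA1 (-5.31, adjusted p = 2.95e-05), DEFA4, a defensin of neutrophil granules (-3.93, adjusted p = 3.59e-05), HLA-DRB4 (-3.85, adjusted p = 0.0037), a class II gene that only some haplotypes carry, and S100A9, the partner of S100A8 (-3.79, adjusted p = 0.0016).

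In the T-lineage list 17 of 22 members rose and 0 fell (17 rose when adjusted over the list alone). With a median of 2.61, the list had an adjusted p = 3.85e-09 (adjusted p = 0.269 with an estimated correlation). SIT1 (3.35, adjusted p = 1.10e-05), UBASH3A, a regulator of T-cell receptor signalling (3.58, adjusted p = 1.27e-05), and LAT (3.83, adjusted p = 2.09e-05) were examples. Of the genes that check the labels, CD3D rose by 3.27 (adjusted p = 1.43e-04) and CD7 by 2.20 (adjusted p = 2.19e-04), and CD79A was not called (-0.64, adjusted p = 0.325). In the B-lineage list 6 of 22 fell and 0 rose (7 fell when adjusted over the list alone). The list median was -0.75 (adjusted p = 0.022, and adjusted p = 0.696 with an estimated correlation). The cortical thymocyte list was not called (adjusted p = 0.117): 6 of 13 members rose and 1 fell (6 and 1 when adjusted over the list alone), with CD4 (1.59, adjusted p = 1.16e-04) and CD1D, an antigen-presenting molecule (2.28, adjusted p = 0.0026), among those that rose. In the NOTCH target list 4 of 10 rose and 0 fell (7 rose when adjusted over the list alone), with HEY1 (2.11, adjusted p = 3.04e-05) and TRIB2, a pseudokinase (3.12, adjusted p = 0.0018), as examples. Its members had a median log2 difference of 1.24 (adjusted p = 0.014, and adjusted p = 0.269 with an estimated correlation).

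Among the lists of other cell types, 22 of 27 fibroblast and matrix genes rose and 0 fell (23 and 1 when adjusted over the list alone), COL6A3 among them (4.69, adjusted p = 2.46e-08). Camera gave the list an adjusted p = 3.08e-14 at a median of 2.51, and adjusted p = 0.140 with an estimated correlation. In the macrophage list 11 of 20 rose and 0 fell (11 rose when adjusted over the list alone). Over all its members the median was 1.15 (adjusted p = 6.41e-04, and adjusted p = 0.343 with an estimated correlation). In the endothelium list 6 of 15 rose and 1 fell (6 and 1 when adjusted over the list alone). With a median of 0.50, it had an adjusted p = 0.021 (adjusted p = 0.402 with an estimated correlation). In the lymph node chemokine list 5 of 15 rose and 0 fell (6 rose when adjusted over the list alone). The list median was 1.16 (adjusted p = 0.0051, and adjusted p = 0.379 with an estimated correlation). In the granulocyte list 13 of 18 fell and 0 rose (14 fell when adjusted over the list alone), with S100A12 (-3.21, adjusted p = 4.46e-04) beside DEFA4 and S100A8. Its members had a median log2 difference of -1.79 (adjusted p = 3.60e-08, and adjusted p = 0.269 with an estimated correlation). In the erythroid list 11 of 15 fell and 0 rose (12 fell when adjusted over the list alone), and HBD, HBB and CA1 had its lowest adjusted p-values. Camera gave the list an adjusted p = 2.53e-08 at a median of -2.55, and adjusted p = 0.269 with an estimated correlation.

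In the cell cycle list 16 of 32 members rose and 0 fell (20 rose when adjusted over the list alone). Over all its members the median was 1.09 (adjusted p = 7.48e-07, and adjusted p = 0.518 with an estimated correlation). AURKA (3.35, adjusted p = 3.35e-06), RRM1, a subunit of ribonucleotide reductase (1.60, adjusted p = 1.05e-04), and TOP2A, the topoisomerase of dividing cells (2.48, adjusted p = 1.39e-04), were examples, though 1 probe set of RRM1 was called higher and the other lower (-0.75). In the immediate early and heat shock list 8 of 19 fell and 2 rose (9 and 2 when adjusted over the list alone), with DUSP1 (-3.10, adjusted p = 5.30e-06) and FOS (-2.75, adjusted p = 9.92e-05) as examples. With a median of -0.91, the list had an adjusted p = 0.0019 (adjusted p = 0.472 with an estimated correlation). In the oxidative phosphorylation list 10 of 30 fell and 1 rose (12 and 1 when adjusted over the list alone). The list median was -0.46 (adjusted p = 0.0010, and adjusted p = 0.585 with an estimated correlation). In the ribosomal protein list 34 of 36 fell and 0 rose (35 fell when adjusted over the list alone), RPL38 (-1.55, adjusted p = 1.42e-05) and RPL30 (-1.23, adjusted p = 5.96e-05) among them. Its members had a median log2 difference of -1.12 (adjusted p = 8.59e-20, and adjusted p = 0.269 with an estimated correlation). The number of ribosomal genes called depended on the scaling, with 10 lower after quantile normalization (median -0.31) and 36 after division by the 75th percentile (median -1.38). With the actin 3'/5' ratio as a covariate 490 genes were called, 472 of them among the 3040, and with that covariate the cell cycle list (adjusted p = 0.058) and the B-lineage list (adjusted p = 0.197) were not called.

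Genes called in both T-lineage groups against B-ALL were compared to see what the T-lineage diseases share. There were 506 such genes with the same direction, 305 higher and 201 lower, and 11 with opposite directions. Ranked by the smaller of their differences, the 8 largest shared increases were in SH2D1A, LCK, TRAT1, LAT, CD3G, CD1B, ALDH1A2 and CD3D. Whether T-cell genes are more frequent among the shared genes than among others was not tested. LCK, the kinase that starts T-cell receptor signalling, was higher by 3.93 in T-ALL (adjusted p = 0.0012) and by 4.06 in T-LL (adjusted p = 1.74e-04). Lower in both were FLT3, a receptor of early progenitors (-3.07, adjusted p = 0.0010, and -3.25, adjusted p = 1.18e-04), IRS2, an adaptor of insulin signalling (-3.04, adjusted p = 6.31e-04, and -3.22, adjusted p = 5.96e-05), and MME, the CD10 antigen of B-cell precursors (-2.93, adjusted p = 0.016, and -2.76, adjusted p = 0.0089). LCK, FLT3, IRS2 and MME, and CD1B and ALDH1A2 in this place, were chosen after their values were seen. Independent lists would share 88.9 higher and 52.5 lower genes. Simulations of unchanged groups that share the B-ALL arrays gave at most 0 shared genes, which only reflects that hardly any gene is called without a change. Across genes, which are not independent replicates, the correlation of the log2 differences was 0.52 against a median of 0.45 in the simulations, and the covariance was 0.360 against 0.0563. When T-ALL and T-LL were each compared with their own part of the B-ALL arrays, a median of 117.5 higher and 66.5 lower genes were shared over 20 splits, where independent lists of the same sizes would share a median of 35.2 and 19.7. The correlation was then 0.36. With the actin 3'/5' ratio as a covariate 33 genes were shared. In T-LL minus B-ALL that covariate ended the calls of LCK (3.01, adjusted p = 0.132), CD1B (2.09, adjusted p = 0.536), ALDH1A2 (1.39, adjusted p = 0.630), FLT3 (-1.78, adjusted p = 0.235), IRS2 (-2.79, adjusted p = 0.051) and MME (-0.90, adjusted p = 0.730).

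Genes called in T-LL against both marrow groups were compared to see what sets the lymphoma tissue apart from marrow of either lineage. There were 1283 with the same direction, 933 higher and 350 lower, and 7 with opposite directions. C3, COL3A1, FN1, VWF, CCN1, SPARCL1, C1S and A2M were higher than in both, and CXCL8, HBD, S100A8, HBB, CA1, TSC22D3 and KLF6 were lower than in both. A2M was higher by 5.44 than in T-ALL and by 4.28 than in B-ALL (adjusted p = 1.77e-11 and 1.98e-09), and TSC22D3 differed by -3.49 and -3.39 (adjusted p = 1.23e-06 and 1.08e-06). Independent lists would share 258.8 higher and 65.5 lower genes, and the simulations again gave at most 0, for the same reason. The correlation across genes was 0.69 against 0.52 in the simulations, and the covariance 0.556 against 0.0698. When each comparison had T-LL arrays of its own, a median of 438.5 higher and 143.5 lower genes were shared over 20 splits, against 96.0 and 19.5 for independent lists. The correlation was then 0.55. With the actin 3'/5' ratio as a covariate 377 genes were shared.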

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

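Of the tests given here, the search for a partner of a swap among the B-ALL arrays, the means of mature B markers on their own, the choice of genes anew without each array, the model with the actin ratio as covariate and the counts without the arrays in doubt were chosen after the result was seen. An array is listed below when its gap to the nearest array of its group is a larger share of the group's range than Dixon's 95% critical value allows. This held for 43 of 295 groups of 9 or 10 arrays, where chance would give about 14.8 if values were normal and groups independent. Some values lie at the floor and many genes vary together, so nothing is concluded from the excess. All values are log2 intensities, with the nearest other array of the group beside them.

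T-ALL 1 stood apart from the other T-ALL arrays in lineage genes. It was the lowest in CD3D (8.06, next 11.12), CD3G (6.03, next 8.90), LAT (6.94, next 10.56) and SH2D1A (5.70, next 10.35), and its T-lineage list mean was 6.35 (next 8.20). It was the highest in CD24 (13.33, next 7.76), BLNK (8.64, next 5.61), HLA-DMA (9.40, next 6.64), INSR (9.35, next 5.67) and IRS2 (11.79, next 8.21), and its B-lineage list mean was 7.63 (next 6.19). The T-lineage minus the B-lineage mean was -1.28 on it (next 2.24). It was also the highest T-ALL array in VWF (5.88, next 3.66) and C3 (3.59, with all others at the floor). T-LL 2 was the lowest T-LL array in SH2D1A (3.14, next 8.13), UBASH3A (3.14, next 6.02) and the T-lineage list mean (6.02, next 7.83).

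For these 2 arrays a swap with a B-ALL array of the series was argued against, since 0 of 10 B-ALL arrays had a T-lineage minus B-lineage mean above 0 (the highest was -0.67). Normal mature B cells stay open: on T-ALL 1 markers of mature minus precursor B cells were -2.03, inside the B-ALL range of -2.89 to -0.76, but the other T-ALL arrays (-3.45 to -1.30) lay below -0.76 too, so the limit set beforehand decides nothing, and its mean of mature markers, 6.31, was the highest in T-ALL (others 4.43 to 5.88). Open for T-ALL 1 too is a wrong label or B-lineage leukaemia cells in the sample, but the data cannot show which. Without these 2 arrays, 1335 genes outside the T-lineage, B-lineage and HLA class II lists were called between T-ALL and B-ALL. On T-ALL 1, 68.3% of them were nearer the B-ALL than the T-ALL mean. The share was 7.22% to 49.9% on the other T-ALL arrays and 58.0% to 85.8% on the B-ALL arrays, each with genes and means found without it. On T-LL 2 the markers of mature minus precursor B cells were 0.93, above all B-ALL arrays, but through a low mean of precursor markers (5.61) and not a raised mean of mature ones (6.54, against 5.50 to 8.44 on the other T-LL arrays), so they stay open there too. Its share of genes nearer B-ALL, 50.9%, was just above the 25.8% to 50.1% of the other T-LL arrays, so a wrong label or a B-lineage lymphoma stays open there.

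The collagen and matrix genes higher in T-LL than in T-ALL were set against RNA quality and against stromal cells of the tissue. Shorter RNA in the T-LL arrays was argued against as the whole cause: with the actin 3'/5' ratio as a covariate the list median was 2.84, against 2.80 without it, and 22 of 27 members were still called. Whether stromal cells are the source stays open. Over the 9 T-LL arrays the members had a mean pairwise correlation of 0.478, above the 95th percentile of 0.094 for 1000 random lists (median 0.030). The random lists were matched on mean intensity alone, so any genes that vary together could pass, whichever cells express them. Of the list's 27 measured genes, 0 stand in another list. How much the lymphoma cells themselves express stays open, because every T-LL sample was tissue and every T-ALL sample marrow.

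The ribosomal protein genes lower in T-LL than in B-ALL were set against scaling, RNA quality and dilution by stroma. Scaling may account for much of the difference: the list median of -1.12 was -0.31 after quantile normalization, though -1.38 after division by the 75th percentile. With the actin ratio as a covariate the median was -0.72 and 1 of 36 members was called, but the members' median SE grew from 0.23 to 0.36, since the actin ratio differs between the groups, and the role of RNA quality cannot be told apart from the group. Dilution by stromal cells stays open too, with an r of 0.29 between the fibroblast and ribosomal list means over 9 T-LL arrays (exact permutation p = 0.450, adjusted p = 0.450 over 5 relations; rho 0.12, exact permutation p = 0.776; r = 0.28 without the 2 farthest arrays). A lower level in the lymphoma cells was not tested.

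Other arrays stood apart in single genes or lists. Among T-LL arrays, T-LL 9 was the lowest in C3 (3.14, next 7.81), RPL31 (11.99, next 12.72) and the oxidative phosphorylation list mean (9.03, next 9.49). T-LL 3 was the highest in CDH5 (7.20, next 5.85) and the lowest in SIT1 (5.62, next 7.19). T-LL 1 was the highest in HEY1 (10.96, next 8.84). T-LL 5 was the highest in S100A8 (10.81, next 6.53) and in the HLA class II list mean (9.85, next 8.40).

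Among T-ALL arrays, T-ALL 2 was the highest in CDH5 (4.26, next 3.57) and T-ALL 7 in CCN1 (5.21, next 3.43). T-ALL 4 was the lowest in COL4A1 (3.14, next 4.52) and the highest in CXCL13 (4, next 3.50). T-ALL 9 was the lowest in UQCRC2 (10.20, next 10.86). T-ALL 10 was the highest in CLEC10A (5.76, next 4.42) and in the dendritic cell list mean (6.21, next 5.43).

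Among B-ALL arrays, B-ALL 6 was the highest in FN1 (8.78, next 5.36), CCN1 (8.61, next 4.97) and UBASH3A (3.72, with all others at the floor). B-ALL 7 was the lowest in HBB (8.41, next 12.06) and HLA-DPA1 (7.77, next 11.16) and the highest in TRAT1 (5.53, next 4.31). B-ALL 2 was the highest in C3 (3.41, next 3.28). B-ALL 4 was the highest in VWF (3.94, next 3.39) and the lowest in the adhesion and homing list mean (6.14, next 7.02). B-ALL 3 was the highest in the oxidative phosphorylation list mean (10.74, next 10.16), and B-ALL 9 in the dendritic cell list mean (6.35, next 5.80).

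Chance alone is an unlikely source of the counts of genes in the 3 comparisons with the values and model reported. Of 100 splits of the samples, the real one included, 1 gave as many as the 1037 genes of T-ALL minus B-ALL (highest other split 741), 1 as many as the 2170 of T-LL minus T-ALL (654) and 1 as many as the 3040 of T-LL minus B-ALL (203). The first count has the smallest margin: it was 717 without T-ALL 5, 735 with the compared groups alone and 324 with the actin ratio. These lie below 741, but the splits were not repeated under those settings. For the 506 genes shared by both T-lineage groups and the 1283 that set T-LL apart from both marrow groups, 1 of 100 splits each gave as many (highest other 0 and 6). That follows from the few genes called in other splits and does not show that the overlaps exceed what the calls themselves would give. For the counts of lists called with the preset correlation, 4 of 100 splits gave 12 or more in T-ALL minus B-ALL. The highest other split gave 13, above the real count, so chance is not excluded. The count was 8 after quantile normalization and without B-ALL 6. Nor can chance be excluded for T-LL minus T-ALL, where 20 of 100 splits gave 12 or more (highest other 16), or for T-LL minus B-ALL, where 11 of 100 gave 13 or more (highest other 16).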

How the results depend on the processing

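The alternatives that keep the identical columns as 2 arrays, leave out the 2 arrays in doubt or add the actin 3'/5' ratio as a covariate were chosen after seeing the data. With 1 array left out at a time, the genes called ranged from 717 (without T-ALL 5) to 1363 (without T-ALL 1) in T-ALL minus B-ALL, from 1788 to 2340 in T-LL minus T-ALL and from 2689 to 3115 in T-LL minus B-ALL. The lists called ranged from 8 to 14, 12 to 14 and 12 to 14, the genes shared by the T-lineage groups from 375 to 696 and those setting T-LL apart from 1134 to 1370.

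The total counts of genes, lists and shared genes that moved by more than 1.5 times did so under a few settings. With the actin ratio as a covariate, 324, 1416 and 490 genes were called, and the overlaps were 33 and 377. The median SE over all genes grew from 0.34, 0.35 and 0.34 to 0.38, 0.42 and 0.52, since this covariate differs between the groups, and the share of the change that comes from RNA quality was not tested. With the fibroblast and granulocyte list means as covariates, 2 genes were called in T-LL minus T-ALL, covariates that themselves separate those groups. With an estimated correlation 1, 1 and 0 lists were called, and fry, which asks whether a list's genes move one way and not whether they differ from other genes, called 6, 13 and 14. All other alternatives gave total gene counts within 1.5 times of those reported, such as 1501, 2467 and 3121 with the identical columns kept, 1446, 3105 and 3186 with array weights, and 735, 2523 and 2856 with the compared groups alone. Counts of higher or lower genes alone, and counts within a list, could move more, as given above for the scaling.

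As a replicate block, the numbers of the titles gave 942, 2350 and 3152 genes, overlaps of 445 and 1456, and 11, 12 and 12 lists. Arrays of different groups were also correlated across genes after each gene's group mean was subtracted. Those with the same number then had a mean correlation of 0.0331, 0.0367 and 0.0325, and those with different numbers -0.0037, -0.0036 and -0.0035. Against 10000 random pairings the mean of the same-number pairs did not pass (one-sided p = 0.176, 0.160 and 0.128, adjusted p = 0.176 in each), so the numbers were not taken to pair the samples.

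The choice of named genes left out lower-ranked members of the lists. Of the genes named in the sections above, 0 reversed under any alternative, where the runs with 1 array left out count as 1 setting per gene. The variance model, the fit of the compared groups alone and the test of all probe sets could not reverse a gene. They leave the difference of its chosen probe set as it is. Other probe sets were not counted here, though ATP5F1C in T-LL minus T-ALL and FN1 and RRM1 in T-LL minus B-ALL each have 1 called the other way. In T-ALL minus B-ALL, 471 of 503 results kept their side of the threshold, 25 lost the call and 7 gained it, in T-LL minus T-ALL 696 of 711 with 8 and 7, and in T-LL minus B-ALL 550 of 572 with 22 and 0. Over all genes that the naming rule allows, in all 30 lists, 83 of 825, 89 of 1281 and 116 of 1535 results lost the call. Of these genes 1 changed sign, THBS1 in T-LL minus B-ALL, from -0.83 (adjusted p = 0.0072) to 0.17 (adjusted p = 0.588) with the mean of all probe sets. Over all called genes that mean reversed the call of IFNAR2 and NUP160 in T-LL minus T-ALL and of C6orf62, IGFBP5 and MAX in T-LL minus B-ALL, named here after their values were seen. The actin ratio ended 35 of the calls of named genes, among them SH2D1A (3.67, adjusted p = 0.058), CD3D (2.32, adjusted p = 0.136), TOP2A (1.97, adjusted p = 0.097), LCK, FLT3, IRS2, MME, CD1B and ALDH1A2 in T-LL minus B-ALL, MEF2C (-2.60, adjusted p = 0.214) and MME in T-ALL minus B-ALL, and BUB1B (1.27, adjusted p = 0.068) and MCM3 in T-LL minus T-ALL. Quantile normalization ended those of CD79A, DUSP1 and RPL22 in T-ALL minus B-ALL (adjusted p 0.052, 0.085 and 0.055), RPL31 in T-LL minus T-ALL (0.079) and RPL30 in T-LL minus B-ALL (0.068). The mean of all probe sets ended those of BCL2, ICAM2, RPL22, ATP5F1C (-0.37, adjusted p = 0.233) and RRM1 (0.43, adjusted p = 0.152), and a floor at the 40th percentile those of CD1B and CD72. Among lists with a median not close to 0, that of 1 changed sign, stem and progenitor in T-LL minus B-ALL, from -0.41 to 0.46 with the actin ratio, and it was not called in either. Lists with a small median were left out of this count. Examples in T-LL minus T-ALL are HLA class I and antigen processing (0.08) and stem and progenitor (0.04). Low signal limits the folds: the floor of 8.8 holds down genes such as C3 and CIITA, which were at the floor on 8 and 7 of 9 T-ALL arrays.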

Other observations

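Of the tests in this part, those of the stem and cortical lists were chosen after the result was seen. Some genes of dendritic cells were higher in T-LL than in T-ALL, but the list was not called: 4 of 11 measured members rose and 0 fell (5 rose when adjusted over the list alone; median 1.13, adjusted p = 0.053, adjusted p = 0.468 with an estimated correlation). CD209, a lectin of dendritic cells and macrophages, was 3.84-fold higher (log2 difference 1.94, SE 0.46, limma adjusted p = 0.0029, 9 of 9 arrays above the T-ALL mean). CLEC10A, a lectin of conventional dendritic cells, rose by 1.64 (adjusted p = 0.0059), and IRF8, a transcription factor of dendritic cells that B cells also express, rose by 1.93 (adjusted p = 0.0098). The list mean was 6.34 ± 0.69 (SD, n = 9) in T-LL, 5.31 ± 0.38 (n = 9) in T-ALL and 5.64 ± 0.28 (n = 10) in B-ALL. The list was called after quantile normalization (adjusted p = 0.025), after division by the 75th percentile (adjusted p = 0.017), with the actin ratio as a covariate (adjusted p = 0.017), with the identical columns kept (adjusted p = 0.047) and without the 2 arrays in doubt (adjusted p = 0.037).

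Genes that remodel the matrix differed in a few members. In the list of matrix proteases and their inhibitors 4 of 20 rose and 0 fell in T-LL against T-ALL (4 rose when adjusted over the list alone), and the list was not called (median 0.68, adjusted p = 0.245). TIMP3, an inhibitor of metalloproteases, rose by 2.53 (adjusted p = 4.13e-04), and MMP9, a gelatinase, rose by 2.38 (adjusted p = 0.0021), each above the T-ALL mean in 9 of 9 arrays.

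Of the 30 lists, 17 were called in at least 1 comparison and 13 in none with the values as deposited. The lists called in none were HLA class I and antigen processing, stem and progenitor, dendritic cell, epithelium and thymic epithelium, NK and cytotoxic T cell, plasma cell, adhesion and homing, matrix proteases, interferon response, glycolysis and hypoxia, apoptosis, MAPK and RAS signalling, and glucocorticoid and chemotherapy response. For interferon response the adjusted p was 0.089 in T-ALL minus B-ALL, 0.766 in T-LL minus T-ALL and 0.381 in T-LL minus B-ALL, with medians of 0.39, 0.16 and 0.52, and it was called in the first with the actin ratio as a covariate (adjusted p = 0.016). The glucocorticoid list, of interest for the treatment of these diseases, had medians of 0.01, 0.11 and -0.05 (adjusted p 0.766, 0.766 and 0.868). Epithelial genes, which would include those of the thymus, had a median of -0.11, a mean of 0.20 and a camera direction of lower in T-LL minus T-ALL, so the sign depends on the summary, and 1 of 13 members rose (adjusted p = 0.828). Camera asks how a list differs from the other genes, and the median over all genes was 0.13 in T-LL minus T-ALL. Several lists not called there had a median above 0 and a camera direction of lower, such as HLA class I and antigen processing (median 0.08), cortical thymocyte (0.16) and stem and progenitor (0.04).

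A hypothesis of a maturation axis among the T-lineage samples was tested with the means of the stem and progenitor list and the cortical thymocyte list, which share 0 measured genes with each other. Over the 9 T-ALL arrays the means were inversely related (r = -0.87, exact permutation p = 0.0056, adjusted p = 0.028 over 5 relations, and rho = -0.82, exact permutation p = 0.011, adjusted p = 0.054). Without the 2 arrays farthest from the median on the stem list, r was -0.92. Without T-ALL 1, whose lineage genes go against its label, r was -0.87 (exact permutation p = 0.014, adjusted p = 0.036), rho was -0.79 (exact permutation p = 0.028, adjusted p = 0.070), and r was -0.73 when the 2 farthest arrays were left out too. The adjusted p of rho did not pass in either case. This is what arrays arrested at different stages would give, and may point to a mix of early and cortical T-ALL. In T-LL r was -0.42 (exact permutation p = 0.260, adjusted p = 0.325, and rho = -0.25, exact permutation p = 0.521), -0.40 without the 2 farthest arrays and -0.69 without T-LL 2 (exact permutation p = 0.071, adjusted p = 0.118), so the question stays open there too. Whether the relation differs between T-ALL and T-LL was not tested.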
